A study of Mus musculus with 4 samples.

How the data were processed

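RNA sequencing was done on 4 libraries of C2C12 myoblasts, 2 with vehicle and 2 with recombinant GDF10 for 6 h. The deposited table holds whole-number read counts per gene, not normalized, which the authors made from their reads. Per the submitters' processing notes the tools were FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0, StringTie 1.3.3b and DESeq2 1.12.4, with genome build mm10; the notes as used here give no role or order. The counting tool, gene annotation and use of strand are not given in the sources used here, and reads from overlapping genes, antisense genes, paralogs and pseudogenes may thus have been split between them or counted for the wrong one. Per the labels' protocols total RNA was extracted with Trizol and treated with DNase. The dose of GDF10 is not given there.

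The table listed 51826 gene identifiers, of which 51633 were found in GENCODE release M21, which gave symbols, positions on mm10 and exon lengths; 193 were not found and kept their identifiers. Groups and replicate numbers were taken from the sample titles. Total counts were 35597310, 29641165, 29944193 and 35057429 in vehicle 1, vehicle 2, GDF10 1 and GDF10 2, with TMM factors of 1.00, 0.999, 1.00 and 0.995. A count of 3 corresponded to 0.0843 to 0.101 CPM. The gene with most counts, mt-Co1, took 0.939% to 1.08%, and mitochondrially encoded genes took 2.27% to 2.56%.

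Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 15467 holding 99.9% of counts in each library. Libraries were scaled by TMM, dispersions were estimated robustly, and glmQLFit and glmQLFTest compared GDF10 with vehicle without covariates. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold and no fold threshold. The standard error of a log2 fold change was taken from the fold change and its F statistic, and 95% intervals from the same. The coefficient of variation between replicates, from the common dispersion, was 14.3%. The p-values measure the spread between these 4 libraries only. A fold against a group at 0 was bounded with 3 counts in each of its libraries.

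Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 32 lists with at least 5 tested members, and with an estimated correlation and fry beside it. The lists, tests, alternatives and the rule for named genes were set before the data were examined. By that rule the text names, among called genes with a log2 CPM of at least 1, separated groups and a symbol that is not a predicted or clone name, the 12 with the largest fold change in each direction (if fewer than 5 passed in a direction, filled to 5 with those of lowest p), the 5 genes of lowest p, up to 4 genes of lowest p from each list, and 25 genes fixed by name. The text picked among these for room, by lowest p, and 1 gene fixed by name is not reported here. Called genes with predicted names, their overlapping neighbours, marker genes given by count and genes called only by DESeq2 were named after their values were seen.

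The tests were tried on simulated data with the means, library sizes and trended dispersions of the 4 libraries, 15467 genes and 200 changed genes, in 5 simulations of GDF10 against vehicle. The changed genes were drawn only from those with a mean CPM of at least 5, so the recovery rates do not cover genes below it. The gene test recovered 38% of genes changed 1.5-fold, 87.6% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 31 of 845 calls, or 3.67%, were false. A list raised by 0.25 on the log2 scale was found in 5 of 5 simulations with a preset correlation and in 0 of 5 with an estimated one. With the preset correlation 1 other list was called over these simulations. Genes were drawn independently, so the simulations do not test whether the preset correlation suits lists of genes that vary together. With no gene changed, 20 simulations gave 0 to 1 calls with trended dispersions, and 4 to 22 calls, with a median of 15, when each gene kept its own estimated dispersion.

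The alternatives were DESeq2 size factors, upper quartile scaling and total counts, no filter or a CPM of at least 1 in 2 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, the replicate number as a block, each library left out in turn, and adjusted p thresholds of 0.1 and 0.01. Chosen after seeing the data were counts summed over clusters of genes that share exon bases on either strand, genes that share none, and log2 CPM with each library's trend with exon length or GC content removed (loess, span 0.3).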

Results

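Gene expression was measured by RNA sequencing in C2C12 cells, a mouse myoblast line that can be grown as dividing precursors or induced to form myotubes. The cells were kept in growth medium and given recombinant GDF10, a secreted ligand of the TGF-beta superfamily, or vehicle for 6 h. Each group held 2 libraries, which the labels describe as biological replicates. Total counts were 35597310 and 29641165 in the vehicle libraries and 29944193 and 35057429 in the GDF10 libraries, and between 21130 and 21748 genes had at least 1 count per library. Pearson correlations of log2 CPM across genes were 0.987 between the vehicle libraries, 0.984 between the GDF10 libraries and 0.983 to 0.986 across the groups. The value of the GDF10 pair thus lay within the range across groups. Counts differed beyond sampling noise in every pair, with chi-square values of 13.8 to 27.1 per degree of freedom, so no library repeated another.

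The comparison asked which transcripts differ in myoblasts after 6 h with GDF10. Few genes passed the test. Xpnpep3, an aminopeptidase gene, rose 3.14-fold, and Pacsin2, a gene of membrane bending and endocytosis, rose 1.78-fold. Dnajb4, a heat shock co-chaperone gene, fell 2.15-fold, and Smurf1, which encodes a ubiquitin ligase that targets SMAD proteins, fell 1.68-fold. Of 15467 genes tested with edgeR's quasi-likelihood test, 25 passed a Benjamini-Hochberg adjusted p of 0.05, 13 higher and 12 lower with GDF10, and 15 of them differed at least 2-fold. An unadjusted p under 0.05 was reached by 918 genes, 378 higher and 540 lower, where 773 would be reached by chance. In 5903 genes, or 38.2%, both GDF10 libraries lay on the same side of both vehicle libraries, against 33.3% by chance. All 25 called genes were among them, which adds no support to the calls, since the test favours genes with separated groups. The median absolute log2 fold change was 0.12, beside a median standard error of 0.13. The split of replicate 1 against replicate 2 gave 23 calls and the crossed split 6, and simulations with no gene changed gave 0 to 1 calls with trended dispersions and 4 to 22 when each gene kept its own. The number of calls was 56 with DESeq2, 11 with limma-voom and 9 without robust dispersion estimates. Ube2v1, Xpnpep3, Pacsin2, Scamp4, Pheta1, Dnajb4 and Gm20431 passed in both of the latter fits and Pigk with limma-voom, at 0.0473. Smurf1 passed in neither, at 0.0582 and 0.0654, nor did Tmem170b, at 0.0791 and 0.0654, Synpo2, Krr1, Pcdh7, Tmem189, Trim39, Ccnyl1, Fam110b, Ccnd3, Larp4b and Tardbp, at 0.0570 to 0.127 with limma-voom and 0.0587 to 0.123 without robust estimates. It was 44 without vehicle replicate 2, 112 without GDF10 replicate 1 and 224 without GDF10 replicate 2; 11 of the 25 genes were kept without vehicle replicate 1 and 13 without vehicle replicate 2.

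Among genes higher with GDF10, Ube2v1, which encodes a ubiquitin-conjugating enzyme variant (ENSMUSG00000078923; mm10 chromosome 2, 167607638 to 167632095) went from 27.8 ± 2.35 to 115.7 ± 5.88 CPM (mean ± SD, n = 2 per group), a log2 fold change of 2.06 with a standard error of 0.10 and an adjusted p of 0.000533 in edgeR's quasi-likelihood test. The summed CPM of Ube2v1, the gene model Gm20431 that overlaps it and Tmem189 differed by 0.12 on the log2 scale. Tmem170b, a transmembrane protein gene, rose from 3.65 ± 0.533 to 14.3 ± 2.14 CPM (log2 fold change 1.97, adjusted p = 0.0149). Xpnpep3 (ENSMUSG00000022401; chromosome 15, 81400138 to 81457482) rose from 13.0 ± 1.64 to 40.9 ± 1.305 CPM (log2 fold change 1.65, adjusted p = 0.00652). Synpo2, which encodes an actin-binding protein of the muscle Z-disc, rose from 15.3 ± 2.05 to 33.1 ± 1.62 CPM (2.17-fold, adjusted p = 0.0285). Pacsin2 rose from 138 ± 2.02 to 245 ± 7.41 CPM, and the protocadherin gene Pcdh7 from 117 ± 0.936 to 222 ± 23.4 CPM. Krr1, a ribosome biogenesis gene, Pigk, of GPI anchor transfer, Tmem189, Trim39 and Ccnyl1 rose by log2 fold changes of 0.96, 0.95, 0.91, 0.91 and 0.78. Without vehicle replicate 1 the adjusted p was 0.0551 for Synpo2, 0.0784 for Krr1 and Pacsin2, 0.0589 for Pigk and 0.0991 for Pcdh7, and without vehicle replicate 2 it was 0.0878 for Synpo2, 0.0628 for Pacsin2 and Pcdh7 and 0.0683 for Pigk, while Krr1 passed at 0.0412. Tmem189, Trim39 and Ccnyl1 passed in neither of those fits, at 0.0784, 0.115 and 0.185 without vehicle replicate 1 and at 0.0986, 0.155 and 0.104 without vehicle replicate 2.

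Among genes lower with GDF10, Scamp4 (ENSMUSG00000113949; chromosome 10, 80602872 to 80615783), of vesicle traffic, fell from 104 ± 4.37 to 15.8 ± 1.28 CPM, a log2 fold change of −2.71 with a standard error of 0.10 and an adjusted p of 0.000135, while the sum with the genes it overlaps had a log2 fold change of 0.08 (adjusted p = 0.840). Pheta1, of endosomal traffic, fell from 15.9 ± 0.860 to 2.70 ± 0.651 CPM (log2 fold change −2.56, adjusted p = 0.00819), and Fam110b from 6.09 ± 0.224 to 1.21 ± 0.198 CPM (log2 fold change −2.33, adjusted p = 0.0149). Ccnd3, the cyclin D3 gene (ENSMUSG00000034165; chromosome 17, 47505051 to 47599691) fell from 76.1 ± 7.08 to 25.6 ± 4.75 CPM (log2 fold change −1.57, adjusted p = 0.0231), and its sum with the overlapping Bysl had an adjusted p of 0.0983. Dnajb4 fell from 55.2 ± 0.481 to 25.7 ± 1.43 CPM. Tardbp, which encodes the RNA-binding protein TDP-43, fell from 123 ± 5.12 to 72.1 ± 0.0126 CPM, and Larp4b, another RNA-binding protein gene, from 75.3 ± 1.21 to 43.0 ± 2.36 CPM. Smurf1 (ENSMUSG00000038780; chromosome 5, 144876495 to 144965847) fell from 149 ± 5.19 to 89.0 ± 1.68 CPM (log2 fold change −0.75, adjusted p = 0.0156). Without vehicle replicate 1 the adjusted p was 0.0589 for Ccnd3, 0.134 for Tardbp, 0.115 for Larp4b and 0.0991 for Smurf1, and without vehicle replicate 2 it was 0.0683 for Tardbp, 0.0814 for Larp4b and 0.107 for Smurf1.

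**Figure D1:**
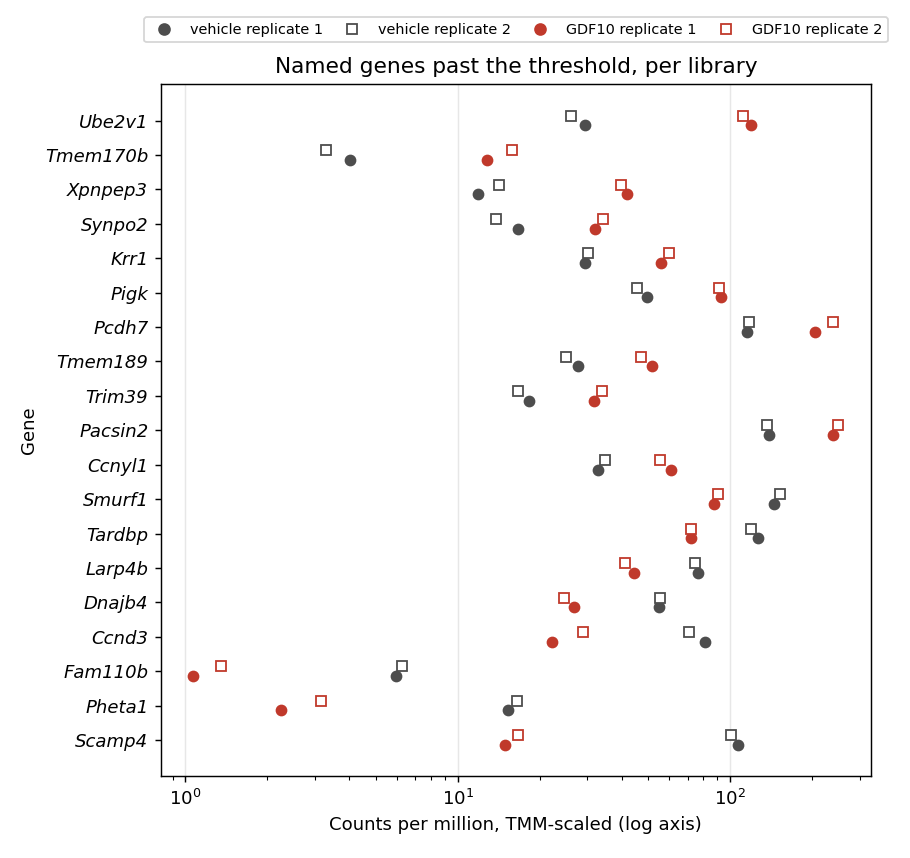
CPM of the named genes past the threshold, on a log axis, with 1 point per library; filled circles are replicate 1 and open squares replicate 2, black for vehicle and red for GDF10. For each gene shown both GDF10 points lie on the same side of both vehicle points, as for Xpnpep3, at means of 13.0 and 40.9 CPM.

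Some called genes overlapped other annotated genes whose counts went the opposite way. Gm20431, a gene model on chromosome 2 that overlaps Ube2v1 and Tmem189, had 3343 and 3006 counts in the vehicle libraries and 0 in both GDF10 libraries, at least 1050-fold lower against a floor of 3 counts per library (adjusted p = 1.77e-05). The counts of Gm20431, Ube2v1 and Tmem189 together were 5387 and 4519 with vehicle and 5148 and 5539 with GDF10, a ratio of 1.09 in CPM. On chromosome 10, Scamp4 fell while Gm49322, which shares exon bases with it, had 134 and 206 counts with vehicle and 3120 and 3374 with GDF10 (adjusted p = 0.189 with edgeR and 1.20e-70 with DESeq2). Scamp4, Gm49322 and Adat3 together gave a ratio of 1.06. Gm20605 fell 2.46-fold, and its sum with the overlapping Lrch4 and Sap25 gave a ratio of 1.007. Ccnd3 overlaps Bysl, whose log2 fold change was 0.0035 with an adjusted p of 0.997, and their sum gave a ratio of 0.664. Gm26712, which overlaps Pyurf, had 118 and 135 counts with vehicle and 2 in each GDF10 library. Gm17114 had 0 counts with vehicle and 54 and 60 with GDF10, at least 19.0-fold higher, C330021F23Rik had 4 and 2 counts with vehicle and 108 and 68 with GDF10, and the pseudogene Gm6977 had 44 and 38 counts with vehicle and 0 with GDF10, at least 13.5-fold lower. These bounds cover counting error only. Of the 25 called genes 13 shared exon bases with another tested gene, or 52.0%, against 24.9% of all genes tested. So did 9 of the 23 genes called for replicate 1 against replicate 2 and 3 of the 6 of the crossed split. The values of the 13 genes are uncertain because the counting rule and its use of strand are not given in the sources used here. When counts were summed over genes sharing exon bases, an alternative chosen after seeing the data, 13 clusters passed, and 3 of the 13 called genes that share exon bases, Pcdh7, Tardbp and Krr1, lay in one of them. In edgeR's test of the summed counts Ccnd3 with Bysl had a log2 fold change of −0.59, against −1.57 for Ccnd3 alone (adjusted p = 0.0983). Ccnyl1 with its neighbour had one of 0.69, against 0.78 for Ccnyl1 alone (adjusted p = 0.0700).

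**Figure D2:**
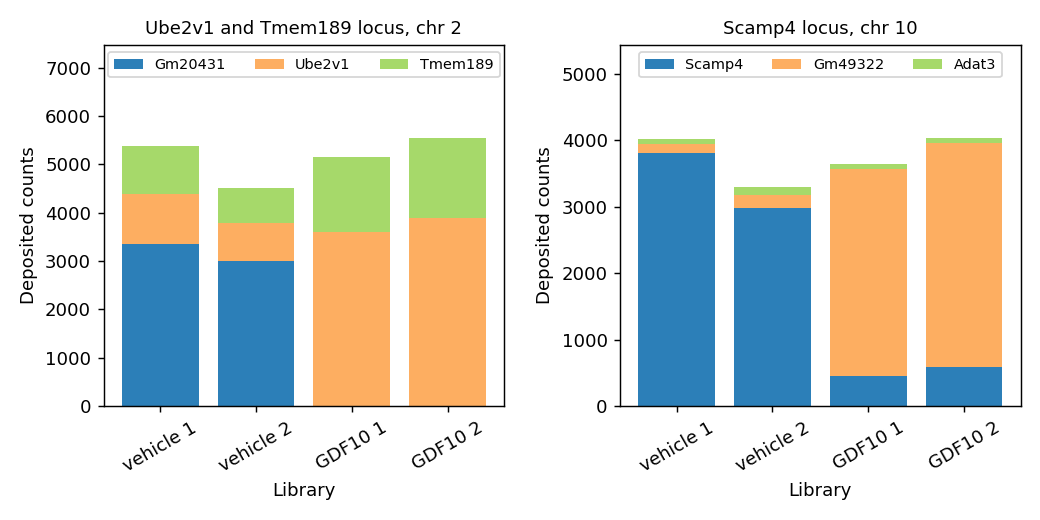
Deposited counts per library at the locus of Ube2v1 and Tmem189 and at the locus of Scamp4, as stacked bars starting at 0, with 1 colour per annotated gene. Gm20431 filled 3343 and 3006 counts in the vehicle libraries and 0 in the GDF10 libraries, while the bar totals at that locus ran from 4519 to 5539.

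Gdf10 itself had 0 counts in all 4 libraries, which allows at most 0.0843 to 0.101 CPM. Receptors of the superfamily were present: Tgfbr2 stood at 193 ± 0.0504 CPM with vehicle and 191 ± 3.21 with GDF10 (log2 fold change −0.01, 95% interval −0.17 to 0.15), and Bmpr2 at 79.1 and 67.6 CPM (log2 fold change −0.23). Tgfbr1, Tgfbr3, Acvr1b, Acvr2a and Acvr2b had log2 fold changes of −0.23, −0.10, 0.05, −0.35 and −0.28. The early SMAD target genes fixed by name did not pass the test. Id1 had a log2 fold change of −0.02 (95% interval −0.23 to 0.19), Id3 −0.03 (−0.24 to 0.18), Smad6 0.09, Smad7 0.15 (−0.09 to 0.39) and Skil −0.39 (−0.93 to 0.16). Id2, an inhibitor of differentiation, had a log2 fold change of −0.41 with an unadjusted p of 0.00303 and an adjusted p of 0.546. Of the 42 TGF-beta and activin SMAD2/3 targets tested, 1 fell (Smurf1) and none rose, and the count was the same adjusted over the list alone; camera's adjusted p was 0.743. Of 25 BMP SMAD1/5 targets 1 fell, and 2 were lower when adjusted over the list alone, Smurf1 and Id2 (camera adjusted p = 0.601). Among 35 receptors and antagonists 0 passed either way, with Grem1, a BMP antagonist, at a log2 fold change of −0.34 (unadjusted p = 0.00604, camera adjusted p = 0.855).

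Myogenic regulators were expressed in both groups and did not pass the test. Myod1 stood at 54.4 ± 1.15 and 57.2 ± 0.445 CPM (log2 fold change 0.07, 95% interval −0.12 to 0.27), Myf5 at 26.0 and 22.9 CPM (log2 fold change −0.18), and Myog, which drives terminal differentiation, at 23.8 ± 0.0888 and 32.0 ± 4.46 CPM (log2 fold change 0.43, unadjusted p = 0.00929, adjusted p = 0.748). Myh3, Ckm and the fusion gene Mymk had log2 fold changes of −0.27, 0.11 and 0.28, and Acta1, skeletal actin, of 0.27 (adjusted p = 0.815). Of 36 genes of myogenic differentiation and fusion 0 passed over all genes tested and 0 adjusted over the list alone, with 3 higher at an unadjusted p under 0.05 by edgeR (camera adjusted p = 0.201), and of 19 myoblast identity genes 0 passed either way (camera adjusted p = 0.890). The atrophy ligase genes Fbxo32 and Trim63 had log2 fold changes of −0.11 and 0.01, and 0 of 23 FoxO and atrophy targets passed either way (camera adjusted p = 0.528). Of the 25 genes fixed by name, 24 were tested, 0 passed, and 3 had an unadjusted p under 0.05 in edgeR: Id2, Myog and Tgfbr1.

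Levels of markers of other cell types ranged widely. No such list passed the test of GDF10 against vehicle, which does not show which cells were present. Summed over each list in vehicle 1, they ran from 18.3 CPM for endothelial and epithelial genes to 5386 for fibroblast genes. Osteoblast and chondrocyte genes summed to 4638 CPM there, mostly Spp1, and myoblast identity genes to 3007. A protocol label names longissimus dorsi muscle while the other labels name C2C12 cells. Counts of the fast myosin gene Myh4 were 4, 0, 0 and 0 in vehicle 1, vehicle 2, GDF10 1 and GDF10 2, those of Pvalb 7, 5, 3 and 0, and those of the leukocyte gene Ptprc 2, 0, 0 and 0; Hbb-bs had 0 in all 4. Others of muscle or blood were detected: Actn3 had 2320, 2027, 2315 and 2561 counts, Myh1 53, 72, 30 and 76, Mb 57, 69, 47 and 92, and the alpha globin gene Hba-a1 149, 125, 183 and 164. Des and Itga7, expressed in myoblasts, averaged 1018 and 657 CPM. None of the marker lists passed: camera's adjusted p was 0.920 for 14 mature muscle genes, whose signal was mostly Aldoa at 1011 CPM, 0.854 for 6 immune and blood genes, 0.472 for 5 endothelial and epithelial genes, 0.348 for 11 osteoblast and chondrocyte genes, 0.404 for 11 adipocyte genes and 0.447 for 15 fibroblast genes. No member of these lists passed over all genes tested, and adjusted over the list alone only the fibroblast gene Ly6a was higher (log2 fold change 0.34). Pparg and Fabp4, of adipocytes, had log2 fold changes of 0.08 and −0.15.

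Of 32 gene lists tested with camera at a preset correlation, 3 passed, all higher with GDF10, and each had an adjusted p of 0.925 with an estimated correlation. With an estimated correlation camera found the list raised by 0.25 in 0 of 5 simulations, so it cannot tell a shift of that size from none. Interferon response genes were positive in 33 of 35 members, with a median log2 fold change of 0.27 (camera adjusted p = 1.59e-07); 0 members passed over all genes tested or adjusted over the list alone, and 14 had an unadjusted p under 0.05 in edgeR, all higher. Irf7, a transcription factor of the interferon response, stood at 26.1 ± 2.15 and 35.4 ± 2.22 CPM (log2 fold change 0.44, adjusted p = 0.620), Oas1a at 19.4 and 26.6 CPM (0.45) and H2-D1, a class I histocompatibility gene, at 91.8 and 112 CPM (0.28). Without GDF10 replicate 2 the interferon list did not pass (median 0.18, adjusted p = 0.0600), and without vehicle replicate 2 its median was 0.13 (adjusted p = 0.00609). Cytosolic ribosomal protein genes were positive in 50 of 54 members, with a median of 0.09 (camera adjusted p = 0.000338), and oxidative phosphorylation genes in 36 of 41, with a median of 0.11 (camera adjusted p = 0.00119); 0 members of either passed over all genes tested or adjusted over the list alone, and 2 and 3 were higher at an unadjusted p under 0.05 in edgeR. Both lists did not pass without GDF10 replicate 1, at 0.583 for the ribosomal genes and 0.391 for oxidative phosphorylation, or without vehicle replicate 2, at 0.154 and 0.310. With fry's directional test 0 lists passed, the smallest adjusted p being 0.481. Across all genes the log2 fold change had a Spearman correlation of −0.26 with exon length and 0.26 with GC content, genes not being independent replicates. Deviations from the mean of the 4 libraries correlated with GC content at −0.15 and −0.20 in the vehicle libraries and 0.16 and 0.17 in the GDF10 libraries. With exon length they correlated at −0.33 in GDF10 replicate 1, without which the ribosomal and oxidative phosphorylation lists did not pass, and at 0.08 in GDF10 replicate 2 and 0.11 and 0.20 in the vehicle libraries.

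**Figure D3:**
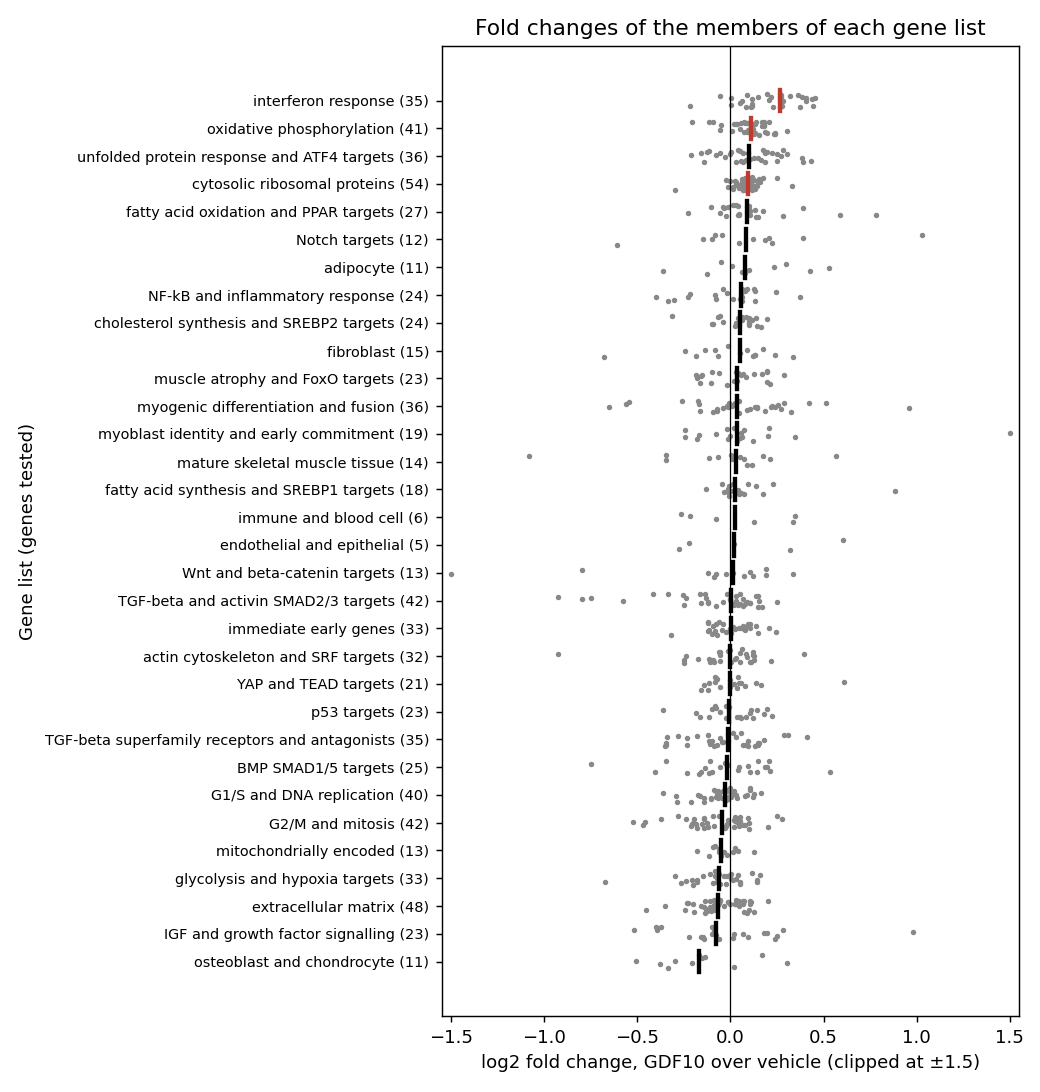
Log2 fold changes, GDF10 over vehicle, of the tested members of each of the 32 lists, with 1 grey point per gene, values beyond 1.5 drawn at 1.5, and a bar at the list's median, red where camera passed with a preset correlation. The interferon response list has its median at 0.27, and the bars of the ribosomal and oxidative phosphorylation lists lie at 0.09 and 0.11.

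Genes of G2/M and mitosis had negative fold changes in 25 of 42 members and did not pass as a list. Of the 42, 0 passed over all genes tested, 2 were lower when adjusted over the list alone, Cenpf (log2 fold change −0.46) and Kif20b (−0.52), and 9 were lower and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0833). The proliferation marker Mki67 went from 191 ± 4.63 to 139 ± 21.1 CPM, a log2 fold change of −0.46 with an adjusted p of 0.620. This list passed as lower in camera with limma-voom, at 0.0105, and with a CPM filter, at 0.0474. It also did so in the fits without vehicle replicate 2 and without GDF10 replicate 1. It did not pass with the exon length trend or the GC content trend removed, and had an adjusted p of 0.925 with an estimated correlation. Of 40 genes of G1/S and DNA replication 0 passed either way (camera adjusted p = 0.447), and the list passed as lower without vehicle replicate 2, at 0.00299. Camera's adjusted p was 0.854 for 23 p53 targets and 0.777 for 33 immediate early genes, with 0 members passing either way.

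In the remaining lists no gene passed over all genes tested. Adjusted over the list alone, 1 was higher among 32 actin cytoskeleton and SRF targets, Actg1 (1955 ± 20.3 to 2567 ± 101 CPM, log2 fold change 0.39; camera adjusted p = 0.890), and 1 among 21 YAP and TEAD targets, the Hippo kinase gene Lats2 (55.3 ± 1.19 to 84.7 ± 2.93 CPM, log2 fold change 0.61, adjusted p = 0.0662; camera adjusted p = 0.890). Among 13 Wnt targets 1 was lower in that way, Wnt11, at 1.38 and 0.403 CPM (log2 fold change −1.77, adjusted p = 0.403; camera adjusted p = 0.890), and fry's test for change in either direction passed for this list, at 0.0176. Adjusted over the list alone 0 members passed in the others, for which camera gave 0.116 for 36 unfolded protein response and ATF4 targets, 0.103 for 27 fatty acid oxidation genes, 0.335 for 18 fatty acid synthesis genes, 0.472 for 24 cholesterol synthesis genes and 48 extracellular matrix genes, and 0.447 for 33 glycolysis and hypoxia targets and 12 Notch targets. It gave 0.476 for 13 mitochondrially encoded genes and 23 genes of IGF and growth factor signalling, and 0.630 for 24 NF-kB targets. The mitochondrially encoded list, on the lower side here, passed as higher with the GC trend removed, at 0.0225. The unfolded protein response list passed as higher without GDF10 replicate 1, at 0.0172, and with limma-voom, at 0.0243. Glycolysis passed as lower without vehicle replicate 1, at 0.00115, extracellular matrix as lower without GDF10 replicate 2, at 0.0339, and myogenic differentiation as higher without vehicle replicate 2, at 0.0401. With an estimated correlation each of the 32 lists had an adjusted p of 0.925. Median, mean and test differed in sign for the TGF-beta, mature muscle, fibroblast, actin, YAP, p53, NF-kB and Wnt lists, none of which passed with camera.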

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

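Tests chosen only after the results were seen are those on summed counts, on genes sharing no exon bases and with length or GC trends removed. The 25 called genes became 24 to 29 under other scalings and filters, which kept 24 or 25 of them, and 37 at an adjusted p of 0.1. They became 6 at 0.01, 56 with DESeq2, which kept all 25, 11 with limma-voom and 9 without robust dispersions, which kept 10 and 8. Summed counts gave 13 and genes sharing no exon bases 12, with fewer units tested. Leaving out 1 library gave 27 to 224 calls; the group left with 1 library was assumed to vary like the other, and the cause of the rise was not tested. The 15 genes of at least 2-fold became 9 with limma-voom, 8 without robust dispersions, 6 with summed counts and 26 to 64 with 1 library left out, and 14 to 20 otherwise. No called gene reversed under the alternatives that give a value per gene. The 3 list calls became 5 with limma-voom, 0 with an estimated correlation and 0 with fry's directional test. They were 3 or 4 under the other settings that kept all 4 libraries. With 1 library left out, not all of the 3 lists passed in each fit, and other lists did. Without GDF10 replicate 1 the median fell from 0.1093 to 0.0282 for oxidative phosphorylation and from 0.093 to 0.0212 for ribosomal genes. The interferon median fell from 0.2655 to 0.1327 without vehicle replicate 2. Scaling moved the median log2 fold change of all genes to at most 0.0141.

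Signs were compared only for called genes and for genes that the naming rule gave and the text reports. Among those that had not passed, fold changes turned in sign, by more than their standard error, in 3 cases. Acvr2b was 0.0982 without GDF10 replicate 1, and Fabp4 and Fbxo32 were 0.1472 and 0.0276 without vehicle replicate 2. With 1 library left out these genes ranged from −0.82, −0.40 and −0.24 up to those values. Values near 0 of Id1, Id3, Tgfbr2, Acvr1b and Trim63 also turned in sign by shifts within their standard error. The cause was not tested beyond the removal of 1 library. With 2 libraries per group at this depth 38% of simulated 1.5-fold changes were recovered, in genes above the CPM limit of the simulations. Recovery in genes below that limit was not measured, and other depths were not simulated.

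With a replicate block 23 genes passed, 20 of the 25 among them, 14 were at least 2-fold, and 4 lists passed, the unfolded protein response list being added at 0.0226. Trim39, Ccnyl1, Ccnd3, Gm6977 and Gm17114 did not pass in that fit, at 0.0602, 0.0548, 0.210, 0.0899 and 0.0568. Deviations of same-numbered libraries from their group means had a correlation of 0.15 over 10099 genes. The labels do not say that the numbers mark a shared batch and there are 2 pairs, so the libraries were not treated as paired. The split of replicate 1 against replicate 2 gave 23 calls and the crossed split 6, so a factor shared by same-numbered libraries cannot be excluded.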

Other observations

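Tests chosen only after the results were seen are the comparison with other splits of the libraries, the count of overlapping partners that moved the other way and their spread, summed counts, and the removal of length and GC trends. The label given to the summed-count test and the tolerance of 0.01 applied to the interferon list were also set after the values were seen.

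DESeq2 called 31 genes that edgeR's quasi-likelihood test did not, 17 higher and 14 lower, and those named here were chosen after their values were seen. Ddr2, a collagen receptor, stood at 91.4 ± 6.17 CPM with vehicle and 201 ± 37.2 with GDF10 (DESeq2 log2 fold change 1.14, adjusted p = 4.65e-11; edgeR adjusted p = 0.1097), and Creb1, a transcription factor of cAMP signalling, at 37.8 ± 9.49 and 13.1 ± 0.650 CPM (−1.52, adjusted p = 6.45e-10; edgeR 0.0785). Pfkfb4, a regulator of glycolysis, had a DESeq2 log2 fold change of 0.97 (edgeR adjusted p = 0.0640), and the ephrin gene Efna1 one of −0.82 (edgeR adjusted p = 0.0640). Lats2 and Actg1 were higher by 0.62 and 0.40, at DESeq2 adjusted p-values of 3.73e-05 and 0.00101. Cenpf, Smc4 and Spc25 had DESeq2 log2 fold changes of −0.46, −0.44 and −0.70 (DESeq2 adjusted p = 0.0172, 0.0108 and 0.0104; edgeR 0.225, 0.215 and 0.183).

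Among the called genes, 13 shared exon bases with another tested gene. Reads assigned to a different overlapping gene may account for 6 of them (Gm20431, Ube2v1, Tmem189, Scamp4, Gm20605 and Gm26712), since a partner moved the other way by at least 0.5 of the change. The same explanation is argued against for 6 others (C330021F23Rik, Pcdh7, Ccnyl1, Ccnd3, Tardbp and Krr1), whose partners did not and varied too little to hide it. For 1, Gm17114, its partners varied by more than its change and the test decides nothing. By definition the explanation does not apply to the 12 called genes that share no exon bases with another tested gene. Whether their reads were shared with untested genes, paralogs or pseudogenes was not tested. After counts were summed over clusters, 3 of the 13 lay in a cluster that still passed. Under the rule written before this test, a share under 0.5 goes with read assignment as the cause. The label was changed afterwards because the sum dilutes a gene such as Ccnd3 with the counts of Bysl. At the loci of Gm20431, Scamp4 and Gm20605, where a partner moved the other way, the summed CPM had ratios of 1.09, 1.06 and 1.007. How many of the other calls come from assignment stays open. The 2 genes with at least 100 counts in each library of a group and 3 or fewer in each of the other, against at most 1 in other splits, are too few to tell such differences from ones unrelated to treatment, and a change in transcript form with GDF10 was not tested.

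The ribosomal protein and oxidative phosphorylation lists may reflect GDF10 replicate 1, and vehicle replicate 2 to a lesser degree, more than the treatment. Their lowest medians with 1 library left out were 0.0212 and 0.0282, both without GDF10 replicate 1. Without vehicle replicate 2 they were 0.0623 and 0.0566. Vehicle replicate 2 differed from vehicle replicate 1 by −0.0542 for the ribosomal list and −0.0957 for the other. GDF10 replicate 2 differed from the vehicle libraries by −0.01 and 0.05 for the ribosomal list and by −0.02 and 0.07 for the other. With the exon length trend removed the medians were 0.051 and 0.0689, from 0.09 and 0.11, and both lists passed at 0.0421, so a part from length bias stays open. GC trends separated the groups across all genes (−0.15 and −0.20 with vehicle, 0.16 and 0.17 with GDF10); removing them gave 0.0929 for oxidative phosphorylation, which argues against GC content as its whole cause but not against a part, and 0.0646 for the ribosomal list, which does not decide. An effect of GDF10 on these lists stays open and cannot be told apart from length bias with 2 libraries per group.

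The interferon response list kept medians of 0.2372 and 0.2182 with the length and GC trends removed and passed in both with camera at the preset correlation, which argues against either as its whole cause. In the main fit the list did not pass with an estimated correlation (camera adjusted p = 0.925) or with fry's directional test (adjusted p = 0.824). A difference carried by 1 library stays open. The median of 0.2655 became 0.1327 without vehicle replicate 2 and 0.1768 without GDF10 replicate 2, where the list did not pass. It was 0.3122 without vehicle replicate 1 and 0.3316 without GDF10 replicate 1. Under the rule written before the test, 0.1327 goes with a difference carried by 1 library, as for the ribosomal and oxidative phosphorylation lists. Only with the tolerance of 0.01, set after the value was seen, was the test taken not to decide. The list differed by −0.16 between the vehicle libraries and by 0.17 between the GDF10 libraries, beside 0.10 to 0.37 across the groups. A response to the recombinant protein preparation, including GDF10 itself, is a candidate explanation that the design could not separate from differences between cultures.

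The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 25 calls, and 1 of the 3 splits gave as many, itself; the highest other, replicate 1 against replicate 2, gave 23, and the crossed split gave 6.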
